A study of Mus musculus with 10 samples.

How the data were processed

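The deposited intensities are linear signals of 28856 transcript clusters on 10 Affymetrix Mouse Gene 1.0 ST arrays, with annotation release na32 on mm9 per the file headers. Per the sample labels, adult DBA/2 testis cells were sorted magnetically with an anti-CD9 antibody and cultured in an Iscove-based medium with 10 ng/ml FGF2, 15 ng/ml GDNF and 1% serum, and the labels name no feeder cells. Per the same labels, total RNA was isolated with TRIzol and RNeasy and labelled with biotin by the WT Terminal Labeling kit. Scanner software, background correction, summarization and normalization are not given in the sources used here. The authors' deposited table also holds intensity means for 0 and 3 weeks, which equal the geometric means of the 2 arrays within 8.9e-07. The fold values of that table are the ratio of the authors' deposited 3 week mean to their 0 week mean.

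Signals were taken as log2 after a floor of 1, with 0 values under it. Of the clusters, 22439 carried 1 gene symbol, 2815 several and 3602 none, and only those with 1 symbol entered the gene tests. Of 20200 distinct symbols, 17440 were current in the reference table (GRCm38.p6, used for names only), 2024 were updated through a single synonym and 736 were kept as given, which left 20174 genes. For the 1333 genes with more than 1 cluster the cluster with the highest mean was used. The values of 701 clusters were equal to those of another cluster.

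Group means of all 5 groups were fitted in 1 linear model per gene with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings), with 5 residual and 4.39 prior degrees of freedom. The median SD within groups was 0.0908. Each comparison was a contrast of that limma fit, and p-values were adjusted by the Benjamini-Hochberg method over all genes, or over the list alone where stated. An adjusted p under 0.05 passed. Every adjusted p in the text comes from limma, and those of lists from its function camera with a preset correlation of 0.01 between genes, adjusted over the 31 lists. Camera asks whether a list moved more than the other genes. As alternatives, camera estimated the correlation for each list, and fry tested with its PValue whether genes moved on balance one way, without comparing them with other genes. SE is the posterior standard error of the contrast.

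The 31 lists were written from general knowledge: immune checkpoint and co-inhibitory ligands; MHC class I and antigen presentation; MHC class II presentation; NKG2D and adhesion ligands of NK cells. Also interferon-stimulated genes, undifferentiated spermatogonia, GDNF- and FGF-responsive genes, differentiating spermatogonia, meiotic prophase, spermatids, Sertoli cells, Leydig cells, peritubular myoid and smooth muscle cells, fibroblasts and mesenchyme, macrophages, endothelial cells, lymphocytes, erythroid and platelet cells. Also DNA replication, mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, p53 targets, immediate early and dissociation response, NRF2 and redox, unfolded protein and amino acid response, piRNA pathway and germ cell RNA, DNA methylation machinery, pluripotency, imprinted genes. Genes named with a comparison are Cd274 and a fixed panel, the 8 largest rises and the 8 largest falls that passed without overlap of the 2 groups, and up to 4 members per list that passed with the largest changes.

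The groups, comparisons, lists, panel, test, threshold and most of the other settings tried were chosen before the data were examined. Those settings were quantile, median and cyclic loess scaling, a filter on dim genes (12777 of 20174 kept), all clusters or their average per gene, a trended robust eBayes, fits of only the groups compared, a minimum of 2-fold, a replicate block, leaving out each array, estimated correlation and fry. Added after seeing the data were fits without the 3 week or the 1 week arrays and cyclic loess for lists.

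The code was tested on simulated data for the 10 arrays. Each gene had its mean over all arrays plus independent normal noise of its SD within groups. Changes were added to the 2 week arrays, and 2 weeks was compared with 1 week. The code recovered 24, 72, 96 and 100% of changes of 1.25, 1.5, 2 and 4-fold and called 8 of 19937 unchanged genes. It found a list shifted by 0.3 and called 0 other lists. Only 50 genes per fold size and that list were changed, far fewer than the genes called in the data. The Benjamini-Hochberg cut-off depends on the share of changed genes, so these rates need not hold for the real comparisons. Since the noise was independent between genes, the simulation cannot show how often lists of correlated genes are called falsely. The assignment of the 0 and 3 week arrays was checked against the authors' deposited means.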

Results

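RNA was measured on 10 arrays in 5 groups of 2 arrays each. The 0 week group held adult DBA/2 testis cells sorted with an antibody against CD9, a surface protein of spermatogonial stem cells and of several other cell types. The 1, 2 and 3 week groups held such cells after that time in culture with GDNF and FGF2, growth factors that maintain spermatogonial stem cells. The 5th group held established GS (germline stem) cells, the long-term cultures of spermatogonial stem cells. The median signal per array was 112 to 125.3 and the lower quartile 59.5 to 73.7. No background level is given with the signals, so genes around or below that quartile are not shown to be above background. Falls to such signals and rises from them are lower bounds whose order is uncertain. Values given with a gene are mean signals (± SD where stated) or mean log2 changes ± SE, each with n = 2 arrays per group. Member counts of a gene list rest on adjustment over all genes, and the counts adjusted over the list alone are added where they differ.

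Each pair of replicate arrays was more alike than any pair of arrays from different groups. Across genes, which are not independent replicates, replicates had r = 0.991 to 0.998, against at most 0.984 between groups, for a 2 week and a 3 week array. The lowest r between groups was 0.707. The 1st principal component held 57.1% of the variance and set the 0 week arrays, at -101 and -99.4, apart from all cultured arrays, at -0.154 to 57.7. The 2nd held 32.7% and placed the 1 week arrays at -62.4 and -65.3 and the 2 and 3 week arrays at 34.0 to 45.0. Of 20174 genes, 15064 differed somewhere among the 5 groups. No label says that replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

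**Figure D1:**
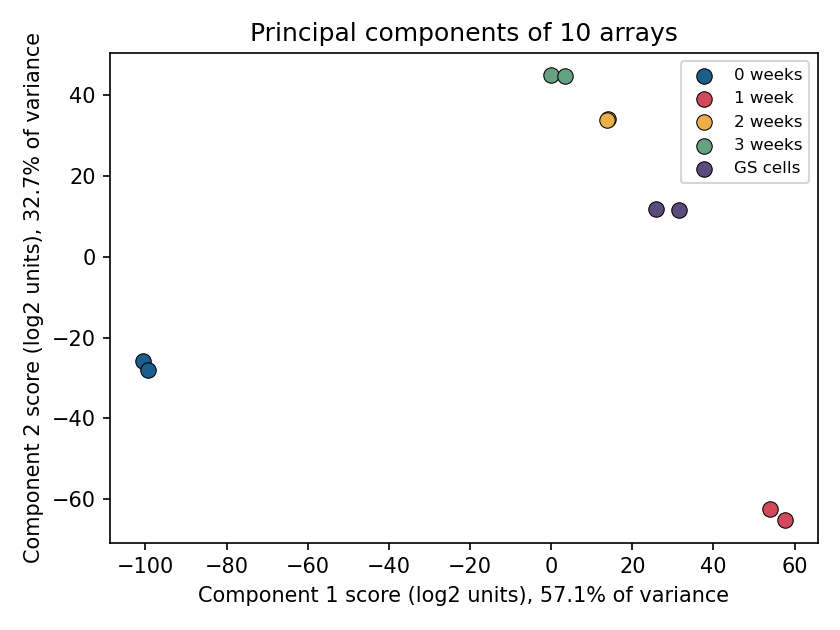
Scores of the 10 arrays on the first 2 principal components (log2 units), coloured by group, 1 point per array. The 0 week arrays lie at -101 and -99.4 on component 1, and the 1 week arrays at -62.4 and -65.3 on component 2.

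Cd274, which encodes the immune checkpoint ligand PD-L1 and is the gene in the title of the series, was at 127.7 ± 6.05 (mean ± SD, n = 2) at 0 weeks and 130.3 ± 8.59 at 1 week on transcript cluster 10462390. It rose to 281.8 ± 9.41 at 2 weeks, a log2 change of 1.11 ± 0.09 from 1 week (n = 2, limma, adjusted p = 3.3e-06), with both 2 week arrays above both 1 week arrays. Cd274 then measured 249 ± 27.4 at 3 weeks and 236.4 ± 4.22 in established GS cells, and neither step passed (-0.18, adjusted p = 0.17, and -0.07, adjusted p = 0.54). Against 0 weeks, Cd274 rose by 1.14 at 2 weeks, 0.96 at 3 weeks and 0.89 in established GS cells (adjusted p = 2.5e-06, 9.6e-06 and 1.3e-05). The change at 1 week was 0.03 (adjusted p = 0.81). Spermatid genes fell in the same comparisons, with medians of -3.42, -3.33 and -3.45, and of -3.5 at 1 week. Changes against 0 weeks are thus relative to sorted cells with more spermatid RNA than the cultured groups. The authors' deposited table gives group means of 127.66 and 248.29 for 0 and 3 weeks and a ratio of 1.94. With quantile scaling Cd274 was lower in established GS cells than at 3 weeks (-0.44, adjusted p = 0.0043), and with cyclic loess too (-0.30, adjusted p = 0.019). The adjusted p of that step ranged from 0.0043 to 0.77 over the alternatives. Pdcd1lg2, the gene of the other PD-1 ligand PD-L2, stayed between 56.1 and 66.5 in all groups and passed in 1 comparison, 3 weeks against 0 weeks (0.21 ± 0.06, adjusted p = 0.018). Its signals lay around the lower quartile of the arrays, and the median of all genes shifted by 0.10 in that comparison.

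Most genes of undifferentiated spermatogonia in the fixed panel were higher at 2 weeks than at 0 weeks. Zbtb16, a transcription factor of undifferentiated spermatogonia, measured 384 at 0 weeks and 344 at 1 week (-0.16 ± 0.06, not passing), then rose to 1575 at 2 weeks (2.19 ± 0.06) and 2022 at 3 weeks (0.36 ± 0.06), and fell to 1647 in established GS cells (-0.30 ± 0.06). The GDNF receptor genes Gfra1 (211, 575, 1008, 514 and 1175 in the order 0, 1, 2, 3 weeks and GS cells) and Ret (226, 482, 1427, 845 and 1491) rose in the first 2 steps, fell at 3 weeks (-0.97 ± 0.08 and -0.76 ± 0.07) and rose again in GS cells (1.19 ± 0.08 and 0.82 ± 0.07). Etv5 (258, 481, 783, 511 and 1626) and Bcl6b (124, 365, 1271, 304 and 1787), both targets of GDNF signalling needed for self-renewal, changed in the same directions as Gfra1 at each step. Id4, a marker of stem cell activity, stayed between 248 and 314 and passed in no comparison.

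Among genes of differentiation, Kit fell at 1 week (282 to 114, -1.30 ± 0.09), rose at 2 weeks (to 248, 1.12 ± 0.09), measured 240.4 at 3 weeks (-0.04 ± 0.09, not passing) and fell in established GS cells (to 188, -0.35 ± 0.09). Stra8, which is induced by retinoic acid at the onset of differentiation and meiosis, stayed between 56.9 and 88.4. Its changes per step were -0.39, 0.22, 0.42 and -0.43 (SE 0.07), all passing. Cd9, the gene of the sorted surface protein, rose at 1 week (183 to 680, 1.90 ± 0.09), fell at 2 and 3 weeks (to 441 and 354, -0.63 and -0.32) and rose in GS cells (to 884, 1.32). The MHC class I genes B2m (757, 4874, 1141, 569 and 1428) and H2-K1 (313, 853, 407, 356 and 462) peaked at 1 week, where the fibroblast list was highest. H2-K1 did not pass at 3 weeks against 2 weeks (-0.19 ± 0.07), and H2-D1 lay only on clusters shared with other genes.

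**Figure D2:**
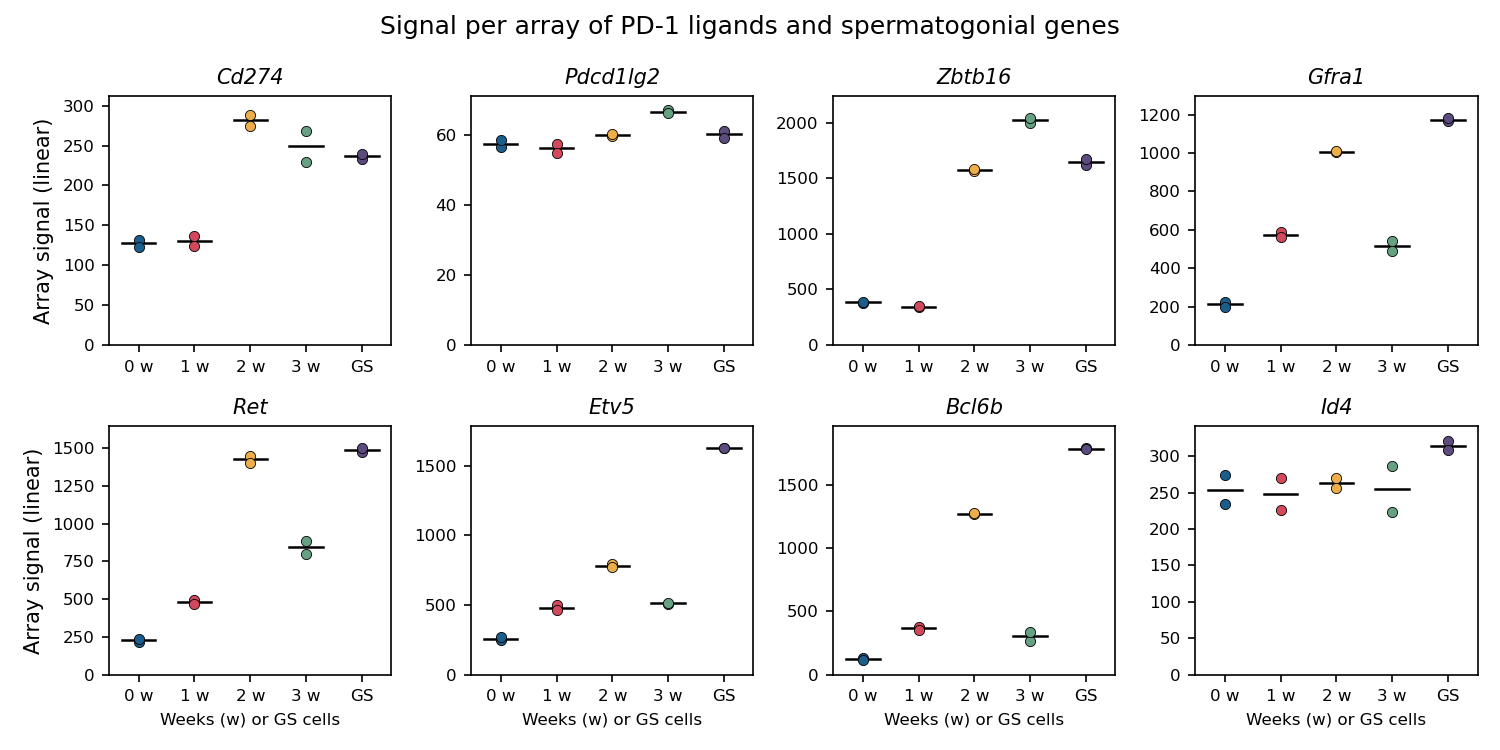
Array signal (linear scale) of the PD-1 ligand genes Cd274 and Pdcd1lg2 and of 6 spermatogonial genes against weeks of culture or GS cells, 1 point per array and a dash at the mean of 2 arrays. Cd274 lay at 127.7 and 130.3 at 0 and 1 week and at 236.4 to 281.8 afterwards.

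The comparison of 1 week with 0 weeks gives the change over the first week of culture. Genes of meiotic cells fell, and genes of fibroblasts and mesenchyme rose. Crisp2, a protein of the sperm acrosome and tail, fell from 4709 to 57.4 (-6.36 ± 0.06 as a lower bound, n = 2), and Ldhc, the lactate dehydrogenase of germ cells, from 4904 to 75.2 (-6.03 ± 0.09). Thbs1, which encodes the matrix protein thrombospondin, rose from 103 to 10370 (6.66 ± 0.16), and Cdkn1a, the cell cycle inhibitor induced by p53, from 174 to 3446 (4.31 ± 0.10). The 8 largest rises, 5.96 to 6.67, were in Tnc, Thbs1, Timp1, Lox, Ptgs2, Saa3, Spp1 and Il1rl1. The 8 largest falls, -6.60 to -6.19, were in Fbp1, Fabp9, Spata4, BC051142, Crisp2, Adam5, Gk2 and Ms4a20, lower bounds since their 1 week signals were 35.8 to 61.7.

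Lists of differentiating and later germ cells fell in the first week. Among spermatid genes 41 of 42 fell and 1 did not pass (42 fell when adjusted over the list alone, median -3.50, camera adjusted p = 1.2e-21, and adjusted p = 0.064 with an estimated correlation). Among genes of meiotic prophase 31 of 34 fell and 3 did not pass (median -1.34, adjusted p = 2.1e-11), including Pgk2 (-4.73 ± 0.06) and Ccna1 (-3.74 ± 0.08). Genes of the piRNA pathway and germ cell RNA fell in 21 of 23 cases, and 2 did not pass (adjusted p = 1.7e-09). Examples are Tdrd6 (-5.24 ± 0.12), a protein of germ cell granules, and Mael (-3.99 ± 0.12), which acts in transposon silencing. Differentiating spermatogonia genes fell as a list (10 fell, 2 rose, 5 did not pass, adjusted p = 0.03, and adjusted p = 0.23 with an estimated correlation). Meioc fell by 3.74 ± 0.18, and the 2 members that rose were Ccnd1 (3.36 ± 0.09), a cyclin of many dividing cells, and Crabp1 (2.74 ± 0.10), a retinoic acid binding protein. Mitosis genes fell (28 fell, 1 rose, 4 did not pass, with 29 falls adjusted over the list alone, adjusted p = 2.2e-08, and adjusted p = 0.2 with an estimated correlation). Examples were Plk1 (-2.62 ± 0.07) and Aurka (-2.40 ± 0.07). DNA replication genes did not pass as a list (5 rose, 13 fell, 14 did not pass, with 6 rises and 14 falls adjusted over the list alone, adjusted p = 0.2), but the list was called lower with quantile scaling (median -0.18) and cyclic loess (-0.34).

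Markers of other testis cells moved apart. All 30 fibroblast and mesenchyme genes rose (median 2.92, adjusted p = 1.5e-15), among them Lox (6.43 ± 0.17) and Fbln2 (5.66 ± 0.08). Leydig cell genes fell (9 fell, 4 did not pass, adjusted p = 4.0e-04, and adjusted p = 0.2 with an estimated correlation), with the steroid enzyme gene Cyp17a1 going from 4992 to 71.3 (-6.13 ± 0.12). Sertoli cell genes fell (15 fell, 6 rose, 3 did not pass, adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation). Examples were Inha (-2.70 ± 0.09) and Clu (-2.20 ± 0.15). Macrophage genes fell (12 fell, 3 rose, 7 did not pass, with 14 falls and 3 rises adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.41 with an estimated correlation). Examples were Fcgr3 (-2.26 ± 0.08) and Aif1 (-2.06 ± 0.09). Peritubular myoid and smooth muscle genes did not pass as a list (3 rose, 7 fell, 4 did not pass, adjusted p = 0.42), with Tagln at 3.16 ± 0.09 and Myh11 at -1.80 ± 0.12. Endothelial genes (2 rose, 7 fell, 8 did not pass, adjusted p = 0.26) and lymphocyte genes (1 rose, 2 fell, 16 did not pass, with 1 rise and 0 falls adjusted over the list alone, adjusted p = 0.26) did not pass either. For 7 erythroid and platelet genes (3 rose, 4 did not pass, adjusted p = 0.52) the median was -0.03, while the mean (0.34) and the test pointed up.

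Several stress and metabolism lists rose beside the fibroblast list. All 21 p53 target genes rose (median 2.19, adjusted p = 1.9e-10), including Ccng1 (3.78 ± 0.18). NRF2 and redox genes rose (14 rose, 3 fell, 1 did not pass, adjusted p = 2.3e-04, and adjusted p = 0.15 with an estimated correlation), among them the heme oxygenase gene Hmox1 (3.69 ± 0.10) and Srxn1 (3.60 ± 0.10). Genes of the unfolded protein and amino acid response rose (20 rose, 3 fell, 2 did not pass, adjusted p = 1.7e-04, and adjusted p = 0.12 with an estimated correlation). Examples were Shmt2 (1.91 ± 0.13) and Xbp1 (1.68 ± 0.08). Immediate early and dissociation response genes rose (12 rose, 4 fell, 5 did not pass, adjusted p = 0.015, and adjusted p = 0.41 with an estimated correlation), but this call ended with quantile scaling (median 0.69) and cyclic loess (0.73). Cholesterol synthesis genes rose (20 rose, 1 fell, 4 did not pass, adjusted p = 5.8e-05), including Hsd17b7 (2.36 ± 0.07). Oxidative phosphorylation genes rose (30 rose, 10 fell, 14 did not pass, with 31 rises adjusted over the list alone, adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation). That call ended with quantile scaling (median 0.13). With cyclic loess the list did not pass, and the test pointed down although the median was 0.05. Glycolysis genes did not pass as a list (13 rose, 7 fell, 2 did not pass, adjusted p = 0.06), with the glucose transporter gene Slc2a3 at -4.37 ± 0.07 and Pgk1 at 3.81 ± 0.14. Each list that rose here did so with fibroblast genes at a median change of 2.92.

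Signalling and immune lists rose as well, again beside the fibroblast list at 2.92. GDNF- and FGF-responsive genes rose (21 rose, 2 fell, 6 did not pass, median 0.87, adjusted p = 1.5e-05). Examples were Ccnd2 (3.36 ± 0.07), Spred2 (3.27 ± 0.08) and the phosphatase gene Dusp4 (3.13 ± 0.13). Undifferentiated spermatogonia genes rose as a list (18 rose, 1 fell, 17 did not pass, adjusted p = 0.013, and adjusted p = 0.14 with an estimated correlation). That call ended with cyclic loess (median 0.00). Its largest rises were in Ddit4 (2.86 ± 0.09), a stress-induced inhibitor of mTOR signalling, and Itgb1 (2.83 ± 0.12), an integrin of many adherent cells. Interferon-stimulated genes rose (23 rose, 1 fell, 13 did not pass, adjusted p = 4.0e-04), including Ifitm3 (2.71 ± 0.20) and Irgm1 (1.51 ± 0.13). Genes of MHC class I and antigen presentation rose (11 rose, 1 fell, 6 did not pass, adjusted p = 0.018, and adjusted p = 0.27 with an estimated correlation). An example was B2m (2.70 ± 0.15). The immune checkpoint and co-inhibitory list, which also holds genes other than ligands, rose (12 rose, 5 fell, 9 did not pass, adjusted p = 0.02, and adjusted p = 0.21 with an estimated correlation). Examples were Pvr (3.77 ± 0.10), Tgfb1 (3.13 ± 0.08) and Lgals1 (2.75 ± 0.11), whereas the enzyme gene Entpd1 fell (-3.17 ± 0.11). Ligands of NK cells rose (4 of 6 rose, 2 did not pass, adjusted p = 0.026, and adjusted p = 0.15 with an estimated correlation), Pvr among them.

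Imprinted genes rose (16 rose, 7 did not pass, with 18 rises adjusted over the list alone, adjusted p = 2.8e-06). Examples were H19 (5.34 ± 0.12) and the growth factor gene Igf2 (3.43 ± 0.07). They too rose beside the fibroblast list at 2.92. MHC class II genes did not pass as a list (2 rose, 6 fell, 3 did not pass, adjusted p = 0.36), nor did DNA methylation genes (7 rose, 3 fell, 4 did not pass, adjusted p = 0.22), with the demethylation gene Tet2 at 1.41 ± 0.12. For pluripotency genes (6 rose, 5 fell, 14 did not pass, adjusted p = 0.82) the median (-0.11) and the test pointed down and the mean (0.09) up. In this comparison 11664 of 20174 genes changed, 6113 higher (52.4%, and 48.0% with cyclic loess) and 5551 lower, of which 2526 and 1987 by at least 2-fold. Of 31 lists 22 passed camera, and the calls of interferon-stimulated, GDNF- and FGF-responsive, meiotic, fibroblast, cholesterol, p53, piRNA and imprinted genes held with an estimated correlation. With a filter on dim genes 15 lists passed, and the calls of MHC class I, NK ligand, undifferentiated and differentiating spermatogonia, macrophage, oxidative phosphorylation and immediate early genes ended.

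The comparison of 2 weeks with 1 week gives the change over the second week. Genes of undifferentiated spermatogonia, meiotic prophase and DNA replication rose, and fibroblast genes fell from their peak. Mael rose from 482 to 3336 (2.80 ± 0.12, n = 2), Dazl, a germ cell RNA-binding protein, from 717 to 3573 (2.32 ± 0.10), and Mcm2, a subunit of the replicative helicase, from 364 to 1578 (2.12 ± 0.08). Prrx1, a transcription factor of mesenchyme, fell from 2942 to 155.8 (-4.24 ± 0.12). The 8 largest rises, 2.62 to 2.80, were in Mael, Zfp640, Rbmy1a1, Sycp1, Nxf2, Tuba3b, Mageb4 and Gm10324. The 8 largest falls, -4.95 to -4.30, were in Il1rl1, Serpinb2, Itga5, Cav1, Thbd, Olr1, Prg4 and Crct1.

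Among genes of undifferentiated spermatogonia 23 rose, 4 fell and 9 did not pass (median 0.71, adjusted p = 3.4e-05), with Epcam (2.26 ± 0.12) and Zbtb16 rising and Itgb1 (-2.04 ± 0.12) and Ddit4 (-2.31 ± 0.09) falling. The piRNA and germ cell RNA list rose (22 of 23 rose, 1 did not pass, median 1.64, adjusted p = 2.9e-11). An example was Ddx4 (2.44 ± 0.11), the germ cell helicase. Meiotic prophase genes rose (26 rose, 2 fell, 6 did not pass, with 27 rises adjusted over the list alone, adjusted p = 3.4e-07). Examples were Sycp1 (2.77 ± 0.23) and Stag3 (2.16 ± 0.07), at signals of 914 and 1179. Differentiating spermatogonia genes rose (11 rose, 2 fell, 4 did not pass, with 13 rises adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.095 with an estimated correlation). Examples were Sohlh2 (2.27 ± 0.08) and Dmrt1 (2.01 ± 0.09). Replication genes rose (30 of 32 rose, 2 did not pass, with 31 rises adjusted over the list alone, median 1.31, adjusted p = 3.3e-14), as did all 33 mitosis genes (median 1.71, adjusted p = 7.1e-17, and adjusted p = 0.091 with an estimated correlation). Examples were Ect2 (2.43 ± 0.11) and Bub1 (2.40 ± 0.12). Each of these lists rose while the fibroblast list fell (median -2.74).

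All 30 fibroblast and mesenchyme genes fell (adjusted p = 4.0e-20), including Postn (-3.76 ± 0.20) and Pdgfrb (-3.61 ± 0.09). Peritubular myoid and smooth muscle genes fell with them (10 fell, 1 rose, 3 did not pass, adjusted p = 2.4e-04, and adjusted p = 0.074 with an estimated correlation). An example was Tagln (-4.03 ± 0.09). The p53 target list fell (19 fell, 1 rose, 1 did not pass, median -1.52, adjusted p = 1.6e-09). Examples were Plk2 (-2.79 ± 0.14) and Perp (-2.71 ± 0.15). Imprinted genes fell (16 fell, 2 rose, 5 did not pass, with 17 falls adjusted over the list alone, adjusted p = 7.9e-06), including Meg3 (-3.28 ± 0.08) and Grb10 (-2.87 ± 0.09). Glycolysis genes fell (16 fell, 3 rose, 3 did not pass, with 17 falls and 4 rises adjusted over the list alone, adjusted p = 9.4e-05, and adjusted p = 0.095 with an estimated correlation). Examples were Pgk1 (-3.47 ± 0.14) and Ldha (-2.25 ± 0.08). NRF2 genes fell (13 fell, 2 rose, 3 did not pass, adjusted p = 5.4e-05, and adjusted p = 0.095 with an estimated correlation), including Srxn1 (-2.97 ± 0.10). Unfolded protein and amino acid response genes fell (19 fell, 4 rose, 2 did not pass, adjusted p = 3.4e-05, and adjusted p = 0.091 with an estimated correlation). An example was Herpud1 (-1.53 ± 0.09). Immediate early genes fell (15 fell, 2 rose, 4 did not pass, adjusted p = 2.0e-05, and adjusted p = 0.2 with an estimated correlation), including Ccn1 (-3.19 ± 0.13). Each of these falls went with that of the fibroblast list, at a median of -2.74.

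The immune checkpoint and co-inhibitory list fell at 2 weeks (12 fell, 2 rose, 12 did not pass, adjusted p = 0.0022, and adjusted p = 0.095 with an estimated correlation), opposite to its member Cd274. Pvr (-3.85 ± 0.10), Cd200 (-2.74 ± 0.11), Lgals9 (-2.46 ± 0.12) and Cd47 (-2.39 ± 0.11) fell, again with fibroblast genes at -2.74. NK cell ligands fell (4 of 6 fell, 2 did not pass, adjusted p = 0.021, and adjusted p = 0.095 with an estimated correlation). Interferon-stimulated genes fell as a list (17 fell, 7 rose, 13 did not pass, with 18 falls adjusted over the list alone, median -0.17, adjusted p = 0.046, and adjusted p = 0.095 with an estimated correlation). That call ended with cyclic loess (median -0.25). Ifitm3 (-2.78 ± 0.20) and Usp18 (-1.39 ± 0.09) fell, and the interferon-induced GTPase genes Gbp2 (1.44 ± 0.09) and Gbp3 (1.41 ± 0.10) rose. The median and the test of the GDNF- and FGF-responsive list pointed up and its mean (-0.02) down (12 rose, 9 fell, 8 did not pass, with 10 falls adjusted over the list alone, median 0.09, adjusted p = 0.77), with Dusp4 at -2.48 ± 0.13 and Lhx1 at 2.01 ± 0.10. Signs of median, mean and test also differed for MHC class II (0.02, -0.13, down), spermatid (0.07, -0.01, up) and endothelial genes (0.03, -0.10, down), none passing. In all, 10259 genes changed, 5167 higher (50.4%, but 45.2% with cyclic loess and 45.3% with a filter on dim genes) and 5092 lower, of which 790 and 1945 by at least 2-fold. Of 31 lists 17 passed, and the calls of undifferentiated, meiotic, fibroblast, replication, p53, piRNA and imprinted genes held with an estimated correlation. The calls of NK ligand and interferon-stimulated genes ended with a filter on dim genes, and that of interferon-stimulated genes also without any 1 of 3 arrays.

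The comparison of 3 weeks with 2 weeks gives the change over the third week, the smallest of the 4 steps in number of genes. Targets of GDNF and FGF signalling fell. Bcl6b fell from 1271 to 304 (-2.08 ± 0.11, n = 2), Lhx1, a transcription factor induced by GDNF, from 573 to 195 (-1.56 ± 0.10), and Egr2 from 833 to 299 (-1.48 ± 0.11). Chac1, a target of the amino acid and unfolded protein response, rose from 142 to 373 (1.39 ± 0.13) and Asns, asparagine synthetase, from 942 to 1724 (0.87 ± 0.08). The 8 largest rises, 1.07 to 1.39, were in Chac1, Snord115, LOC100040223, Upp1, Olfr948, A530040E14Rik, LOC100040235 and LOC100039147. The 8 largest falls, -2.31 to -1.71, were in Mpzl2, Mmp13, Emb, Bcl6b, Nid1, Lcn2, Cd63 and Lox.

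GDNF- and FGF-responsive genes fell (21 fell, 1 rose, 7 did not pass, with 22 falls adjusted over the list alone, median -0.70, adjusted p = 3.1e-13), the only list whose call held with an estimated correlation in this comparison. Undifferentiated spermatogonia genes did not pass as a list (13 fell, 7 rose, 16 did not pass, with 15 falls and 8 rises adjusted over the list alone, adjusted p = 0.2). Replication genes fell (27 of 32 fell, 5 did not pass, with 28 falls adjusted over the list alone, median -0.45, adjusted p = 5.6e-14, and adjusted p = 0.056 with an estimated correlation). An example was Rrm2 (-1.02 ± 0.08). Mitosis genes fell (28 fell, 5 did not pass, with 31 falls adjusted over the list alone, adjusted p = 3.5e-14, and adjusted p = 0.15 with an estimated correlation), including the proliferation marker gene Mki67 (-1.06 ± 0.12). Oxidative phosphorylation genes fell (30 fell, 24 did not pass, with 38 falls adjusted over the list alone, adjusted p = 6.5e-11, and adjusted p = 0.056 with an estimated correlation), and so did cholesterol synthesis genes (15 fell, 10 did not pass, with 16 falls adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.056 with an estimated correlation). An example was Msmo1 (-0.75 ± 0.09). Fibroblast genes fell (18 of 30 fell, 12 did not pass, with 20 falls adjusted over the list alone, median -0.40, adjusted p = 3.8e-08, and adjusted p = 0.062 with an estimated correlation). Examples were Lox (-1.71 ± 0.17) and Thbs1 (-1.69 ± 0.16). The fibroblast list thus moved with each list that fell.

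The p53 (8 fell, 13 did not pass, with 9 falls adjusted over the list alone, adjusted p = 9.7e-05, and adjusted p = 0.062 with an estimated correlation) and immediate early lists (11 fell, 2 rose, 8 did not pass, with 14 falls adjusted over the list alone, adjusted p = 1.0e-05, and adjusted p = 0.31 with an estimated correlation) fell too, including Cdkn1a (-1.10 ± 0.10) and Dusp1 (-1.15 ± 0.10). NRF2 genes fell (7 fell, 1 rose, 10 did not pass, with 8 falls adjusted over the list alone, adjusted p = 0.0085, and adjusted p = 0.36 with an estimated correlation). Interferon-stimulated genes passed as higher (4 rose, 1 fell, 32 did not pass, with 2 rises adjusted over the list alone, median 0.10, adjusted p = 0.049, and adjusted p = 0.15 with an estimated correlation), and so did spermatid (1 rose, 1 fell, 40 did not pass, adjusted p = 0.049, and adjusted p = 0.76 with an estimated correlation) and macrophage genes (22 did not pass, adjusted p = 0.049, and adjusted p = 0.76 with an estimated correlation). These last 4 calls ended with quantile scaling (medians -0.08, 0.03, -0.005 and 0.01) and with cyclic loess (0.01, 0.04, 0.06 and 0.03), where the piRNA list (medians 0.22 and 0.20) and the unfolded protein list (0.19 and 0.18) were called higher. With cyclic loess glycolysis genes were called higher as well (median 0.19, camera adjusted p = 0.028). As deposited, unfolded protein and amino acid response genes did not pass as a list (9 rose, 6 fell, 10 did not pass, with 12 rises and 9 falls adjusted over the list alone, adjusted p = 0.53). The calls of interferon-stimulated, spermatid and macrophage genes also ended when single arrays were left out, and that of NRF2 genes with a filter on dim genes, where unfolded protein and piRNA genes were called higher. The 3 week arrays had the narrowest quartile range of signals, 73.7 to 254.7 and 70.6 to 262.3.

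Signs of median, mean and test differed at 3 weeks, none passing, for immune checkpoint (0.06, -0.02, up), MHC class I (0.01, -0.06, down), meiotic (0.01, -0.03, up), smooth muscle (0.02, -0.14, down), unfolded protein (-0.06, 0.10, up) and imprinted genes (0.00, -0.19, down). Between 2 and 3 weeks 4875 genes changed, 1555 higher (31.9%) and 3320 lower, of which 11 and 132 by at least 2-fold, and 12 of 31 lists passed. The share of higher genes was 49.5% with quantile scaling and 54.8% with cyclic loess, which called 2834 genes, but 26.2% with median centring and 18.4% with a filter on dim genes. Without the 1st or the 2nd 2 week array 1918 and 2068 genes changed, and without the 1st 3 week array 2653.

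The comparison of established GS cells with 3 weeks sets the long-term line against the last time of the primary culture. GDNF and FGF target genes rose, and fibroblast genes rose again. Bcl6b rose from 304 to 1787 (2.57 ± 0.11, n = 2), Dusp6, a feedback phosphatase of ERK signalling, from 429.7 to 2119 (2.30 ± 0.09), and Etv5 from 511 to 1626 (1.67 ± 0.07). Thbs1 rose from 438 to 4716 (3.46 ± 0.16) and Ptgs2, the inducible cyclooxygenase gene, from 179 to 3125 (4.13 ± 0.12). The 8 largest rises, 3.36 to 4.13, were in Ptgs2, Tnc, Il1rl1, Serpinb2, Mpzl2, Mmp13, Thbs1 and Ccn1. The 8 largest falls, -3.42 to -2.37, were in Snord115, Gm26504, Srsy, Lyz2, LOC100039147, Vmn2r122, Nlrp4f and Gm8165.

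GDNF- and FGF-responsive genes rose (23 rose, 1 fell, 5 did not pass, with 24 rises and 2 falls adjusted over the list alone, median 1.39, adjusted p = 2.7e-10). An example was Dusp4 (2.81 ± 0.13). All 30 fibroblast genes rose (median 1.48, adjusted p = 8.6e-15). Examples were Lox (3.16 ± 0.17) and Fbln2 (2.94 ± 0.08). Fibroblast genes thus moved with each list that rose in this comparison. Peritubular myoid and smooth muscle genes rose (8 rose, 6 did not pass, adjusted p = 0.041, and adjusted p = 0.27 with an estimated correlation). An example was Acta2 (2.51 ± 0.25). The call ended with cyclic loess (median 0.17). Undifferentiated spermatogonia genes did not pass as a list (13 rose, 6 fell, 17 did not pass, adjusted p = 0.13), with Mcam at 1.59 ± 0.07. Oxidative phosphorylation genes rose (46 of 54 rose, 8 did not pass, with 48 rises adjusted over the list alone, median 0.49, adjusted p = 7.3e-10, and adjusted p = 0.074 with an estimated correlation). An example was Sdhb (1.13 ± 0.07). The p53 targets rose (17 of 21 rose, 4 did not pass, adjusted p = 4.0e-05, and adjusted p = 0.074 with an estimated correlation), including Tnfrsf10b (1.25 ± 0.07). Immediate early genes rose (18 rose, 1 fell, 2 did not pass, median 1.18, adjusted p = 1.5e-07, and adjusted p = 0.21 with an estimated correlation). Examples were Ccn1 (3.36 ± 0.13), Fosb (2.18 ± 0.11) and Fos (1.73 ± 0.15).

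Replication genes rose (27 of 32 rose, 5 did not pass, adjusted p = 9.1e-07, and adjusted p = 0.17 with an estimated correlation). An example was Mcm4 (1.26 ± 0.10). That call ended with quantile scaling (median 0.17). Mitosis genes rose (15 rose, 1 fell, 17 did not pass, median 0.24, adjusted p = 0.034, and adjusted p = 0.68 with an estimated correlation), but the median was -0.10 with quantile scaling and -0.09 with cyclic loess, neither passing. Cholesterol synthesis (14 rose, 1 fell, 10 did not pass, adjusted p = 0.0063, and adjusted p = 0.11 with an estimated correlation), NRF2 (13 rose, 5 did not pass, adjusted p = 5.3e-04, and adjusted p = 0.21 with an estimated correlation) and imprinted genes (12 rose, 3 fell, 8 did not pass, adjusted p = 0.039, and adjusted p = 0.21 with an estimated correlation) rose, including Txnrd1 (1.49 ± 0.11) and Meg3 (1.17 ± 0.08). Interferon-stimulated (9 fell, 3 rose, 25 did not pass, with 8 falls adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.17 with an estimated correlation) and macrophage genes (7 fell, 1 rose, 14 did not pass, adjusted p = 0.0039, and adjusted p = 0.49 with an estimated correlation) fell, including Oasl2 (-0.94 ± 0.10) and the lysozyme gene Lyz2 (-2.48 ± 0.18), while Ifitm3 rose (2.48 ± 0.20). These 5 calls ended with quantile scaling (medians 0.02, 0.12, 0.16, -0.03 and -0.05) and cyclic loess (0.05, 0.07, 0.23, 0.003 and -0.08). Spermatid genes fell (6 fell, 1 rose, 35 did not pass, with 1 fall and 1 rise adjusted over the list alone, median -0.11, adjusted p = 0.0055, and adjusted p = 0.59 with an estimated correlation). That call ended with quantile scaling (median 0.00).

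The piRNA list did not pass (5 rose, 7 fell, 11 did not pass, adjusted p = 0.31) but was called lower with quantile scaling (median -0.38) and cyclic loess (-0.27). Signs of median, mean and test differed, none passing, for immune checkpoint (-0.03, 0.28, up), MHC class I (-0.01, 0.01, down), MHC class II (-0.08, 0.01, down) and endothelial genes (0.00, 0.16, up). Of the immune checkpoint list Tgfb1 (2.23 ± 0.08), Lgals1 (1.45 ± 0.11) and Pvr (1.43 ± 0.10) rose, beside the fibroblast list at 1.48. Between 3 weeks and established GS cells 9508 genes changed, 6038 higher (63.5%) and 3470 lower, of which 720 and 196 by at least 2-fold, and 14 of 31 lists passed, with the GDNF and FGF and the fibroblast calls holding with an estimated correlation. The share of higher genes was 48.2% with quantile scaling and 50.2% with cyclic loess, but 81.6% with a filter on dim genes. A filter on dim genes ended the calls of smooth muscle, mitosis, cholesterol and imprinted genes, and with it meiotic and piRNA genes were called lower. Leaving out 1 array ended those of smooth muscle, mitosis, imprinted, interferon-stimulated and spermatid genes.

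The comparisons of 2 and of 3 weeks with 0 weeks give the cumulative change of the culture against the sorted cells. At 2 weeks Bcl6b was higher by 3.36 ± 0.11 (n = 2), Ret by 2.66 ± 0.07 and Lhx1 by 2.50 ± 0.10, and Prm1, a protamine of sperm chromatin, was lower, from 12990 to 127 (-6.68 ± 0.17). At 3 weeks Zbtb16 was higher by 2.40 ± 0.06 and Uchl1 by 2.01 ± 0.10, and Prm1 was lower (-6.63 ± 0.17). The 8 largest rises at 2 weeks, 3.34 to 4.43, were in Saa3, Spp1, Slc38a1, Thbs1, Timp1, H19, Bcl6b and Cacng7, and those at 3 weeks, 2.70 to 3.07, in Foxf1, Fscn1, Slc38a1, Timp1, Saa3, Large2, Mageb4 and H19. The 8 largest falls were in Prm1, Crisp2, Fbp1, Spata4, Adam5, Smcp, Plaat5 and Oaz3 at 2 weeks (-6.68 to -6.26), and in Prm1, Spata4, Crisp2, Fbp1, Adam5, Ms4a20, Oaz3 and Gk2 at 3 weeks (-6.63 to -6.04). All but Prm1 fell to 36.7 to 60.8, so these too are lower bounds. The rises of Saa3 and Slc38a1 are also lower bounds, since their 0 week signals were 72.97 and 69.09.

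At 2 weeks the lists of undifferentiated spermatogonia (27 of 36 rose, 9 did not pass, with 29 rises adjusted over the list alone, median 1.07, adjusted p = 2.2e-10), GDNF- and FGF-responsive genes (21 rose, 2 fell, 6 did not pass, adjusted p = 7.6e-07), replication (30 of 32 rose, 2 did not pass, adjusted p = 2.0e-11), cholesterol synthesis (19 rose, 3 fell, 3 did not pass, adjusted p = 1.3e-05) and p53 targets (15 rose, 6 did not pass, with 16 rises adjusted over the list alone, adjusted p = 1.3e-05) rose. Spermatid (41 of 42 fell, 1 did not pass, adjusted p = 5.1e-29) and smooth muscle genes (12 of 14 fell, 2 did not pass, adjusted p = 3.2e-06) fell, and these 7 calls held with an estimated correlation. Mitosis genes rose too (23 rose, 6 fell, 4 did not pass, adjusted p = 0.0016, and adjusted p = 0.52 with an estimated correlation), and so did MHC class I genes (10 rose, 1 fell, 7 did not pass, with 11 rises adjusted over the list alone, adjusted p = 0.0086, and adjusted p = 0.27 with an estimated correlation), including the proteasome genes Psme2 (2.30 ± 0.08) and Psmb10 (1.93 ± 0.13). Imprinted genes rose (10 rose, 3 fell, 10 did not pass, adjusted p = 0.028, and adjusted p = 0.17 with an estimated correlation). The list no longer passed with cyclic loess (median 0.05). That scaling called immediate early genes lower (median -0.44, camera adjusted p = 0.012). Meiotic (18 fell, 8 rose, 8 did not pass, adjusted p = 0.001, and adjusted p = 0.15 with an estimated correlation), Sertoli (16 fell, 1 rose, 7 did not pass, adjusted p = 3.9e-06, and adjusted p = 0.17 with an estimated correlation), Leydig (9 fell, 4 did not pass, adjusted p = 3.9e-06, and adjusted p = 0.15 with an estimated correlation) and macrophage genes (12 fell, 2 rose, 8 did not pass, adjusted p = 0.004, and adjusted p = 0.52 with an estimated correlation) fell. The fibroblast list did not pass (12 rose, 7 fell, 11 did not pass, with 13 rises and 8 falls adjusted over the list alone, adjusted p = 0.15).

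At 3 weeks no list's call held with an estimated correlation. Undifferentiated spermatogonia genes rose (29 of 36 rose, 7 did not pass, with 30 rises adjusted over the list alone, median 1.05, adjusted p = 1.3e-08, and adjusted p = 0.071 with an estimated correlation), as did GDNF- and FGF-responsive (15 rose, 5 fell, 9 did not pass, with 18 rises adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.15 with an estimated correlation) and replication genes (23 rose, 3 fell, 6 did not pass, adjusted p = 9.8e-05, and adjusted p = 0.2 with an estimated correlation). Interferon-stimulated genes rose (15 rose, 3 fell, 19 did not pass, with 2 falls adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.15 with an estimated correlation). Examples were Gbp2 (2.37 ± 0.09) and Irf1 (1.85 ± 0.09). With quantile scaling the list no longer passed, although its median stayed at 0.16 against 0.17 as deposited. MHC class I genes rose as well (9 rose, 2 fell, 7 did not pass, with 10 rises adjusted over the list alone, adjusted p = 0.032, and adjusted p = 0.41 with an estimated correlation), as did cholesterol synthesis (15 rose, 5 fell, 5 did not pass, with 18 rises adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.15 with an estimated correlation) and p53 genes (11 rose, 1 fell, 9 did not pass, adjusted p = 0.031, and adjusted p = 0.2 with an estimated correlation). Immediate early genes fell (14 fell, 1 rose, 6 did not pass, with 15 falls adjusted over the list alone, adjusted p = 3.6e-05, and adjusted p = 0.3 with an estimated correlation). Examples were Jun (-2.28 ± 0.11) and Fosb (-2.07 ± 0.11). Quantile scaling also called macrophage genes lower (median -0.15, camera adjusted p = 0.022). Cyclic loess called pluripotency genes higher (median 0.30, camera adjusted p = 0.03). Meiotic (17 fell, 7 rose, 10 did not pass, with 18 falls adjusted over the list alone, adjusted p = 5.3e-04, and adjusted p = 0.15 with an estimated correlation), spermatid (41 fell, 1 did not pass, adjusted p = 9.5e-28, and adjusted p = 0.12 with an estimated correlation), Sertoli (16 fell, 1 rose, 7 did not pass, adjusted p = 1.5e-05, and adjusted p = 0.2 with an estimated correlation), Leydig (9 fell, 4 did not pass, adjusted p = 2.2e-05, and adjusted p = 0.2 with an estimated correlation) and smooth muscle genes (12 fell, 2 did not pass, adjusted p = 2.5e-06, and adjusted p = 0.098 with an estimated correlation) fell.

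At 2 weeks 9427 genes differed from 0 weeks, 5131 higher (54.4%) and 4296 lower, of which 1202 and 1862 by at least 2-fold, and the share of higher genes was 65.8% with median centring and 41.0% with cyclic loess. At 3 weeks 10882 differed, 6065 higher (55.7%) and 4817 lower, of which 693 and 2113 by at least 2-fold, and the share of higher genes was 64.6% with median centring, 46.1% with cyclic loess and 49.0% with a filter on dim genes. The median change of all genes was 0.10 at 3 weeks (0.11 with quantile scaling, 0.16 with median centring) and 0.14 with median centring at 2 weeks, so changes are relative to these shifts. Camera passed 14 lists at 2 weeks and 13 at 3 weeks. The calls of macrophage and imprinted genes at 2 weeks ended with a filter on dim genes, and that of p53 genes at 3 weeks without 1 array. Signs of median, mean and test differed, none passing, for NK ligand (-0.05, 0.13, up), lymphocyte (-0.02, 0.02, down), erythroid (-0.03, 0.01, down), glycolysis (0.02, -0.29, down) and piRNA genes (0.02, -0.46, down) at 2 weeks. The same held at 3 weeks for immune checkpoint (0.10, -0.09, down), NK ligand (0.14, 0.03, down), fibroblast (0.00, -0.06, down), erythroid (-0.01, 0.08, up), mitosis (0.12, 0.01, down), glycolysis (0.11, -0.32, down) and NRF2 genes (0.17, -0.05, up).

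The comparison of established GS cells with 0 weeks sets the long-term line against the sorted cells. Genes of undifferentiated spermatogonia were higher. Spermatid genes were lower (adjusted p = 0.07 with an estimated correlation). Bcl6b rose from 124 to 1787 (3.85 ± 0.11, n = 2) and Dusp6 from 158 to 2119 (3.74 ± 0.09). Mcam, a surface adhesion molecule, rose from 523 to 3579 (2.78 ± 0.07). Pou5f1, the pluripotency transcription factor gene, rose from 60.8 to 339.5 (2.47 ± 0.13 as a lower bound). The 8 largest rises, 4.57 to 5.77, were in Tnc, Spp1, Thbs1, Timp1, Ptgs2, Mmp3, Serpinb2 and Lox. The 8 largest falls, -6.96 to -6.39, were in Prm1, Crisp2, Fabp9, Fbp1, Spata4, Smcp, Adam5 and Oaz3, lower bounds for all but Prm1 since their signals in GS cells were 38.4 to 60.5.

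Undifferentiated spermatogonia (30 of 36 rose, 6 did not pass, with 31 rises adjusted over the list alone, median 1.50, adjusted p = 1.2e-09), GDNF- and FGF-responsive (23 rose, 1 fell, 5 did not pass, with 24 rises adjusted over the list alone, median 1.78, adjusted p = 1.6e-08), cholesterol synthesis (20 rose, 2 fell, 3 did not pass, adjusted p = 5.3e-05) and p53 genes (20 of 21 rose, 1 did not pass, adjusted p = 1.1e-06) rose, and these 4 calls held with an estimated correlation. Fibroblast genes rose beside them (25 rose, 3 fell, 2 did not pass, with 26 rises adjusted over the list alone, median 0.95, adjusted p = 6.8e-07, and adjusted p = 0.071 with an estimated correlation). Replication genes rose (30 of 32 rose, 2 did not pass, adjusted p = 1.2e-09, and adjusted p = 0.071 with an estimated correlation), including Mcm4 (2.57 ± 0.10). Pluripotency (11 rose, 2 fell, 12 did not pass, adjusted p = 0.021, and adjusted p = 0.26 with an estimated correlation), imprinted (15 rose, 3 fell, 5 did not pass, adjusted p = 0.005, and adjusted p = 0.11 with an estimated correlation) and MHC class I genes (11 rose, 1 fell, 6 did not pass, adjusted p = 0.021, and adjusted p = 0.26 with an estimated correlation) rose, including Dppa4 (1.73 ± 0.07), Sox2 (1.55 ± 0.14) and H19 (3.58 ± 0.12). NRF2 genes rose (13 rose, 3 fell, 2 did not pass, with 4 falls adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.26 with an estimated correlation), while Gstm1, a glutathione transferase gene, fell from 2757 to 208 (-3.73 ± 0.12). Oxidative phosphorylation (35 rose, 8 fell, 11 did not pass, with 36 rises adjusted over the list alone, adjusted p = 0.0023, and adjusted p = 0.19 with an estimated correlation) and unfolded protein genes (17 rose, 5 fell, 3 did not pass, adjusted p = 0.017, and adjusted p = 0.26 with an estimated correlation) rose, calls that ended with cyclic loess (medians 0.03 and 0.08). DNA methylation genes rose (9 rose, 1 fell, 4 did not pass, adjusted p = 0.045, and adjusted p = 0.17 with an estimated correlation). An example was Dnmt1 (1.46 ± 0.08). The list no longer passed with quantile scaling (median 0.34) and cyclic loess (0.12).

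Spermatid genes fell in established GS cells (41 of 42 fell, 1 did not pass, with 42 falls adjusted over the list alone, median -3.45, adjusted p = 6.8e-28, and adjusted p = 0.07 with an estimated correlation). Meiotic (18 fell, 6 rose, 10 did not pass, adjusted p = 2.3e-04, and adjusted p = 0.11 with an estimated correlation), Sertoli (15 fell, 4 rose, 5 did not pass, adjusted p = 4.7e-04, and adjusted p = 0.26 with an estimated correlation), Leydig (9 fell, 4 did not pass, adjusted p = 1.5e-05, and adjusted p = 0.15 with an estimated correlation), smooth muscle (9 fell, 2 rose, 3 did not pass, adjusted p = 0.0087, and adjusted p = 0.15 with an estimated correlation) and macrophage genes (14 fell, 1 rose, 7 did not pass, adjusted p = 2.2e-04, and adjusted p = 0.26 with an estimated correlation) fell. Among Sertoli genes the iron transport gene Trf rose (3.38 ± 0.07), from 152 to 1589. The piRNA list did not pass (9 rose, 10 fell, 4 did not pass, with 11 falls adjusted over the list alone, adjusted p = 0.16) but was called lower with quantile scaling (median -0.38) and cyclic loess (-0.61). Signs of median, mean and test differed, none passing, for endothelial (-0.07, 0.11, down), lymphocyte (-0.04, 0.03, down), erythroid (-0.05, 0.03, down) and glycolysis genes (0.19, -0.04, up). In this comparison 10337 genes changed, 6223 higher (60.2%, and 44.8% with cyclic loess) and 4114 lower, of which 1828 and 1751 by at least 2-fold, and 19 of 31 lists passed. With a filter on dim genes 13 lists passed, and the calls of MHC class I, oxidative phosphorylation, NRF2, unfolded protein, DNA methylation and pluripotency genes ended. Those of MHC class I and DNA methylation genes also ended without 1 array.

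**Figure D3:**
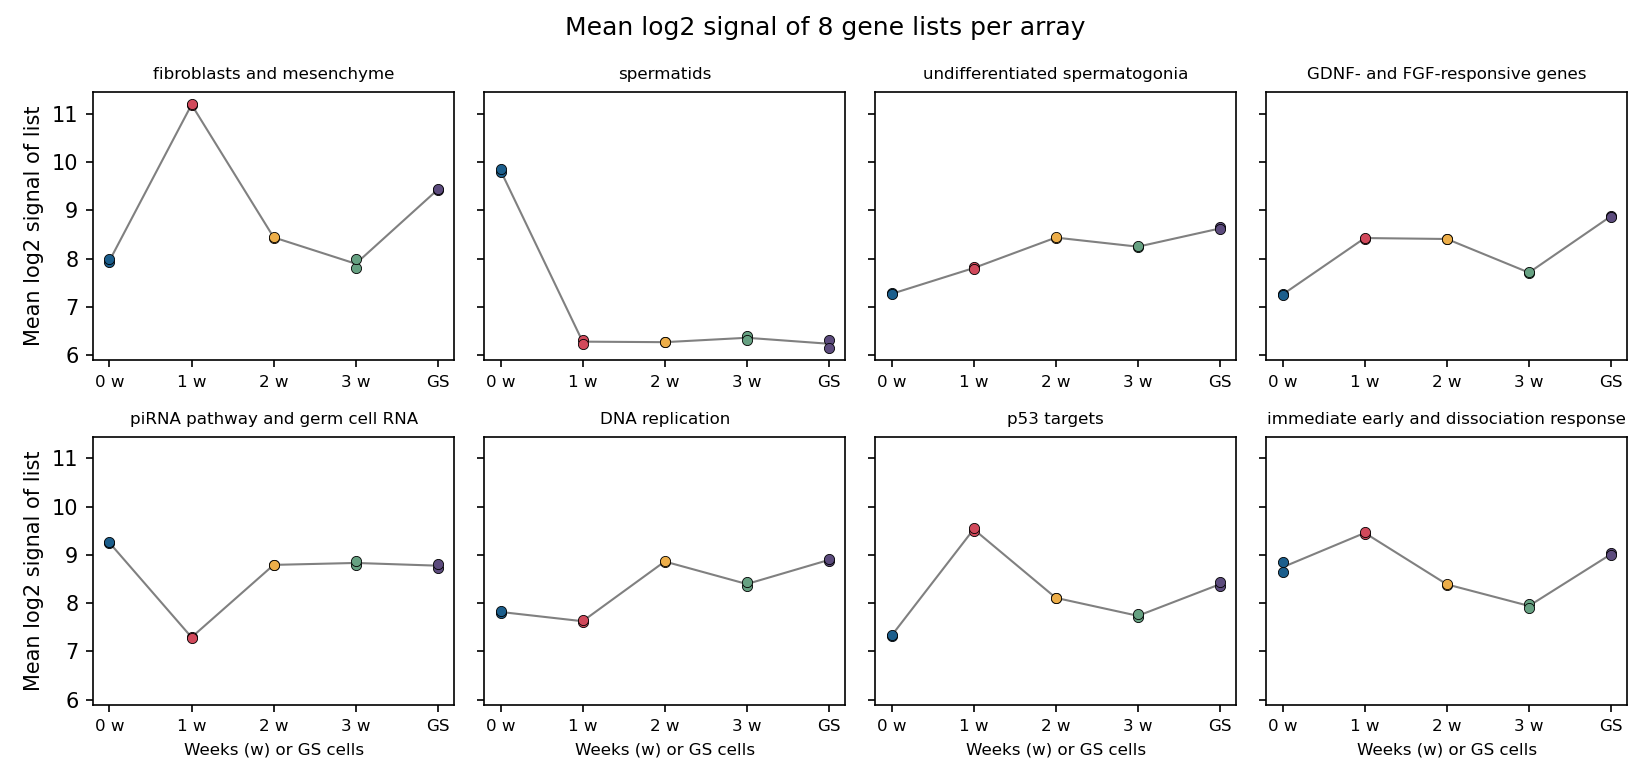
Mean log2 signal of the measured members of 8 gene lists against weeks of culture or GS cells, 1 point per array, lines through group means. The fibroblast list lay at 11.18 and 11.20 at 1 week, 7.80 to 8.45 at 2 and 3 weeks and 9.42 and 9.44 in GS cells, and the spermatid list at 9.79 and 9.86 at 0 weeks and 6.15 to 6.40 later.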

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

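The tests weighed here were chosen only after the results were seen, although quantile scaling, and median centring and cyclic loess for single genes, were planned.

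All 30 fibroblast genes were higher in established GS cells than at 3 weeks. Scaling between arrays is argued against, since the list's median stayed at 1.125 or above with quantile scaling and cyclic loess. Of the genes off the list that were abundant at 1 week and at least 8-fold lower at 2 weeks 99.1%, 114 of 115, rose in GS cells, against 29.9% of all genes. The compared share of all genes was not matched in signal. Thbs1 measured 10370, 1383, 437.9 and 4716 at 1, 2 and 3 weeks and in GS cells, and Fn1 10130, 2353, 1242 and 4775. Of the list's members, 0 of 30 were on another list. Per member, the signal gained after 3 weeks was 0.0192 to 0.632 of that lost from 1 to 2 weeks (median 0.208). The members thus did not return in equal proportion. Stromal cells could be present after the anti-CD9 sort or as feeder cells, which the labels do not name. The share and these ratios cannot separate them from expression within GS cells, which stays open, untested.

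GDNF- and FGF-responsive genes were lower at 3 weeks than at 2 weeks. Scaling between arrays is argued against by a list median of -0.532 or lower with both scalings. A lower share of germ cells as a whole is argued against by the piRNA and germ cell RNA list, with a median of 0.1 and quartiles of -0.16 to 0.23. That list cannot decide on a lower share of undifferentiated spermatogonia among the germ cells, which stays open. The undifferentiated spermatogonia list had a median of -0.08, with 13 falls and 7 rises. Less RNA of stromal cells is argued against by the 20 of 29 members brighter in GS cells than at 1 week, with a median of -0.91, though 10 of 29 members are on another list. A change in growth factor signalling over time in culture could explain the fall and stays open, untested.

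Cd274 was higher at 2 weeks than at 1 week. Scaling between arrays is argued against by a change of 1.141 or more in 3 scalings. An interferon response was left undecided by a list median of -0.17 with quartiles of -0.59 to 0.05, since Gbp2 (1.44) and Gbp3 (1.41) rose while Ifitm3 (-2.78) and Usp18 (-1.39) fell. A higher share of spermatogonia could explain the rise but was not decided. The change of 1.11 lies within the quartiles of the undifferentiated spermatogonia list (0.12 to 1.34) and of the piRNA list (0.74 to 2.14). These ranges are too wide to decide. From 0 to 2 weeks Cd274 rose by 1.14 and the undifferentiated list by a median of 1.07, but the piRNA list by 0.02. From 0 to 1 week the undifferentiated list rose (median 0.3) and the piRNA list fell (-1.4), while Cd274 changed by 0.03. A change within the cells over time in culture stays open, untested.

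The 3602 transcript clusters without a gene symbol were fitted and adjusted apart from the genes. Among them, 227 were at least 2-fold higher and 74 lower at 3 weeks than at 0 weeks. Of the 20174 genes, 693 were higher and 2113 lower by as much. In established GS cells 66 such clusters were at least 2-fold higher and 106 lower than at 0 weeks, against 1828 and 1751 of the genes.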

How the results depend on the processing

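Cyclic loess for lists and the fits without the 3 week or the 1 week arrays were chosen only after seeing the data, and the other alternatives were planned. A repeat on per-sample values of the authors' table had been meant to be made and was not run, since that table holds only group means. Of 111 list calls 29 held with an estimated correlation, and 22 ended with a filter on dim genes. The cause of the differences between settings was not tested. Leaving out an array assumes that the lone sample of its group varies like the other groups. No label says that equal replicate numbers share a source, and correlations of replicate differences between groups ran from -0.067 to 0.584, with 6 of 10 group pairs over 0.1 and 0 under -0.1. All pairs with the 2 week group lay at -0.067 to -0.024, and all pairs without it at 0.31 to 0.584. With the replicate number as a block 12584, 11374, 6695, 10931, 10109, 12117 and 11128 genes changed in the 7 comparisons, 16297 in the F test, and all calls of Cd274 were kept. The block gave 10 lists at 3 against 2 weeks, where the calls of interferon-stimulated and macrophage genes ended, and 18 in GS cells against 0 weeks, where that of DNA methylation genes ended. For GS cells against 3 weeks it gave 15 lists, with lymphocyte genes called lower.

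With quantile scaling, established GS cells against 3 weeks gave Cd274 -0.44, Aurka -0.41, Dmrt1 -0.31, H2-K1 -0.055, Hmox1 -0.073, Irf1 -0.26, Nxf2 -0.27, Plk1 -0.16, Slc2a3 -0.26, a mitosis median of -0.101 and 7 lists passing. Ldha was 0.27 at 3 against 2 weeks, and Kit 0.003 and Stag3 0.066 at 3 against 0 weeks. With the deposited values all these genes but Cd274, and the mitosis list, had the opposite direction.

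With cyclic loess, established GS cells against 3 weeks gave Cd274 -0.30, Aurka -0.35, Dazl -0.27, Dmrt1 -0.29, H2-K1 -0.012, Hmox1 -0.038, Nxf2 -0.28, Plk1 -0.12, a mitosis median of -0.093 and 8 lists passing. Large2 was -0.094 and Mcam -0.009 at 1 against 0 weeks, with an oxidative phosphorylation median of 0.053. At 3 against 2 weeks 2834 genes changed, and the glycolysis list was called higher (median 0.194, camera adjusted p = 0.028). Sdhb was -0.27 at 2 against 0 weeks. In GS cells against 0 weeks Bub1 was -0.53, Cd47 -0.17, Ect2 -0.29, Fosb -0.44, Grb10 -0.092 and Oasl2 -0.31. All genes named here but Cd274 had the opposite direction with the deposited values, as did the test of each list named.

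With a minimum of 2-fold 4513, 2735, 143, 916, 3064, 2806 and 3579 genes changed (steps in order, then 2, 3 weeks and GS cells against 0 weeks), and the calls of Cd274 at 3 weeks (0.96) and in GS cells (0.89) against 0 weeks ended. In the same order, 8, 7, 1, 2, 7, 0 and 4 lists passed with an estimated correlation. With fry 23 lists passed for GS cells against 3 weeks, 26 and 23 at 2 and 3 weeks against 0 weeks, and the direction turned for NRF2 genes at 3 weeks (median 0.175) and endothelial genes in GS cells (-0.071) against 0 weeks. Leaving out 1 array gave 1918 to 5842 genes at 3 against 2 weeks.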

Other observations

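The genes, clusters and values shown in this part were picked only after the results were seen. The comparisons, test and threshold for genes were those chosen before.

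A few genes peaked at 3 weeks and fell in established GS cells. Foxf1, a forkhead transcription factor of mesenchyme, measured 284, 472, 1615, 2376 and 684 in the order 0, 1, 2, 3 weeks and GS cells (n = 2) and passed at each step (0.74, 1.78, 0.56 and -1.80, SE 0.10). Snord115, a family of small nucleolar RNAs, measured 262, 105, 446, 1091 and 111, and the Y-linked Srsy 369, 102, 367, 800 and 148. Vmn2r122 (326, 141, 587, 1070 and 210) and Nlrp4f (326, 138, 586, 1063 and 208) had nearly the same signal as each other in each group. Whether their clusters measure separate RNAs was not tested, so they cannot be taken as independent results. Lyz2, a lysozyme of macrophages, was highest at 2 weeks instead (397, 551, 743, 599 and 104) and fell in GS cells.

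Spp1, Il1rl1, Ptgs2 and Mmp13 peaked at 1 week and were higher in GS cells than at 3 weeks, and were not tested as a group. Spp1, osteopontin, measured 114, 7166, 1955, 629 and 5290 over the same groups, Il1rl1, the IL-33 receptor, 94.7, 5880, 191, 150 and 2136, and Ptgs2 83.9, 6031, 471, 179 and 3125. The matrix protease gene Mmp13 measured 71.0, 2907, 528, 115 and 1319. Mpzl2, an adhesion molecule of epithelia, was highest in GS cells instead (97.7, 263, 668, 137 and 1592). Slc38a1, an amino acid transporter gene, measured 69.1, 598, 1056, 487 and 908, and Large2, a glycosyltransferase gene, 232, 290, 1447, 1524 and 1313.

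Among 3602 clusters without a symbol, 292 were lower and 6 higher by at least 2-fold in established GS cells than at 3 weeks. Of the 20174 genes, 196 were lower and 720 higher by as much. Against 0 weeks, cluster 10395908 rose in GS cells from 137 to 1856 (3.72 ± 0.33) and cluster 10354916 fell from 5052 to 69.5 (-6.18 ± 0.08).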
